A study of Caenorhabditis elegans with 4 samples.

How the data were processed

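Chromatin immunoprecipitation with sequencing (ChIP-seq), which recovers the genomic DNA attached to a protein, was carried out on whole L3 larvae of Caenorhabditis elegans. The worms carried an integrated transgene that expresses the zinc finger protein SEA-2 fused to GFP, together with a copy of unc-119 that rescues the unc-119 mutation of the strain. The labels give 4 biological replicates of 1 group and no contrast between groups. They give a fragment size range of 150 to 350 bp for replicates 1 and 2, and sonication and another source of the worms for replicates 3 and 4.

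The data used are peak lists that the authors deposited, on the builds ce10 and ce11. Per the deposited file records, each replicate's list was called from its own alignment against 1 control file shared by all replicates, a pooled list was called from all 4 alignments against that control, and a final list was kept from the pooled list by thresholding on the irreproducible discovery rate (IDR). The aligner, the peak caller, the IDR threshold and the read numbers are not given in the sources used here, so the depth behind each list is unknown. Each peak has a signal value from the authors' peak caller, whose scale is not stated. The deposited lists also hold the −log10 of a q-value and the summit position of each peak. Signal values were used only to rank or describe peaks within a list. Before any use, the final ce11 list was compared with the pooled list, and its 312 peaks were the 312 strongest peaks of the pooled list by signal value. The final list is therefore a product of all 4 replicates together, and its recovery in a replicate is not independent of that replicate.

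All positions are on ce11, 1-based. The reference was the WBcel235 assembly with Ensembl release 115 gene models, and gene symbols came from RefSeq through the WormBase gene identifiers. No peak in the ce11 lists ended beyond a chromosome of this reference. Coordinates were never converted between builds, and the ce10 lists were used for counts, for shares on X and for overlaps among themselves. Annotated starts in this organism can be trans-splice sites instead of transcription starts, so distances to a start are distances to the annotated one.

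Replicates were compared at equal numbers, through the 312 strongest peaks by signal value of each replicate. The overlap of a pair was the share of summits inside a peak of the other replicate, averaged over both directions, with 1000 circular shifts of the peaks along their chromosomes as the chance level. A final peak was taken as found in a replicate when it shared at least 1 bp with its 312 strongest peaks. Each summit was given 1 annotation class, in the order promoter, 5' UTR, coding exon, 3' UTR, noncoding exon, intron and intergenic. The promoter window ran from 1000 bp upstream to 200 bp downstream of an annotated start, over all genes except pseudogenes and piRNA genes. Class shares and the distance to the nearest protein-coding start were tested against 1000 random placements on the same chromosome, two-sided, for which the smallest p is 0.002. The number of peaks on X was tested against the share of promoter-window length on X with a two-sided exact binomial test.

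A gene was counted as bound when a final summit lay in its promoter window, which says where a summit lies and not that the gene is regulated. Bound genes in 22 lists, fixed before the data were examined, were compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists. The lists of RNA gene types were compared with all other genes. In the heat shock and stress list 2 symbols, and in the hypodermis and seam cell list 2 symbols, matched no gene and were left out. Sequence was read within 50 bp of each summit and in windows centred 250 bp to each side of it. GC content was tested by permutation with 100000 sign flips, and the presence of each of the 2080 canonical 6-mers by Fisher's exact test with Benjamini-Hochberg adjustment. Second copies of the final peaks were searched in the genome with blastn 2.17.0 and were counted from 50 bp and 90% identity.

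The genes named were set by a rule before the data were examined. They are the gene with the nearest annotated start to each of the 20 strongest final peaks, sea-2, unc-119, xol-1 and lin-28 whatever their values, each bound member of the heterochronic and sex determination lists, and up to 6 members by signal value of any other list past an adjusted p of 0.05. Members of further lists, protein-coding neighbours of RNA genes and 10-base words were named after their values were seen. Alternatives covered the number of strongest peaks, the overlap criterion, the promoter window, the assignment of summits to genes, the stronger 50% of the final peaks, the ce10 lists, the sequence window and background, and leaving out each replicate in turn. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only. For a count of 0 the share given as a limit is 3 counts of the total and not an interval bound. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The procedures were tested on simulated data. A planted promoter share of 60% came back as 59.9% with 312 peaks. This follows from the construction, since the same annotation placed and classified the peaks, and it tests nothing. A planted replicate overlap of 40% was recovered as 40.2%, and a planted 6-mer ranked 1 of those tested. In 5 of 100 simulated sets of bound genes a list without enrichment had a p under 0.05 (Fisher's exact test). A list of 30 genes bound at 15% passed a p under 0.0025 in 69 of 100. The simulated genes were bound independently, while in the data 1 peak can bind several genes, which these simulations do not cover. Windows for the planted 6-mer were random genome positions, so a GC difference between summits and flanks was not covered either.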

Results

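The data describe where SEA-2 fused to GFP was found on chromatin in whole L3 larvae. SEA-2 is a zinc finger protein known as an autosomal element of the X to autosome count that sets sex in C. elegans, and it also acts in larval developmental timing. On ce11 the 4 biological replicates had lists of 23684 peaks (replicate 1) and 30000 peaks (replicates 2, 3 and 4). These lists include background regions by design, since they are the input to the IDR step. The pooled list held 3912 peaks and the final list 312, or 7.98% of the pooled list. The pooled list also includes background regions, with −log10 q-values down to 0.017, so some of its weaker peaks can be background. The usual peak width was 340 bp in the pooled and final lists and between 296 and 376 bp in the replicates.

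The strongest final peak lay at V, 1151355 to 1151694, in an exon of the long noncoding RNA gene linc-128 (WBGene00219734), with a signal value of 234 against a median of 73.7 in the final list. It ranked 3, 2, 2 and 3 in replicates 1 to 4. The second peak, at II, 11759305 to 11759573, lay 132 bp upstream of F44E5.4 (WBGene00009691), a gene of the HSP70 chaperone family, with a signal value of 223. That peak was first in replicates 1, 2 and 3 and ranked 74 in replicate 4, and part of its sequence occurs a second time in the genome. The peak at I, 9988792 to 9989131, lay between the divergent histone genes his-67 and his-68 with a signal value of 139.7, and the peak at V, 9546829 to 9547168, lay 106 bp upstream of the histone gene his-37 with a signal value of 118. The bromodomain gene bet-2 had a peak 291 bp upstream (X, 10568812 to 10569151, signal value 136), and nurf-1, which encodes a chromatin remodelling subunit, had a peak 56 bp upstream of an annotated start (II, 14405206 to 14405545, signal value 127).

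Further protein-coding genes nearest to these 20 peaks were Y39E4B.6, coq-3 of ubiquinone synthesis, the protease gene tasp-1, drr-2 and the AAA ATPase gene cdc-48.1, with signal values from 119.8 to 141. The others had an RNA gene as the nearest start. The ncRNA genes F52D10.7 (X, 11605993 to 11606105, signal value 198), F13D11.9 (X, 5812028 to 5812367, 151), C30C11.14 (III, 8446980 to 8447319, 143) and C26C6.12 (I, 7500314 to 7500653, 141) held the ranks 3 to 6. For C30C11.14 the nearest protein-coding start was that of the proteasome gene rpn-3, at 203 bp, and for C26C6.12 that of the bromodomain gene pbrm-1, at 833 bp. The ncRNA genes Y111B2A.34, F47F6.13, Y59A8B.37 and F54F2.13 and the snoRNA gene ZK20.9 completed the 20. The nearest protein-coding start to the F47F6.13 peak was that of the heterochronic gene lin-42, 2993 bp away. Weaker final peaks, at ranks 179 and 255, lay nearer to lin-42, 1400 bp and 348 bp downstream of an annotated start. The replicates differed at some of these sites. The F52D10.7 peak ranked 2, 3 and 1 in replicates 1, 3 and 4 and 4400 in replicate 2, and the ZK20.9 peak ranked 5, 6 and 50 in replicates 1, 2 and 3 and 1872 in replicate 4. The F52D10.7 peak was narrower than the usual 340 bp and overlapped the final peak of rank 49 (X, 11606052 to 11606391). Its ranks need not describe a separate site.

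Promoters held most of the final summits. Of the 312 summits, 230 (73.7%, 95% exact interval 68.5 to 78.5%) lay in a promoter window, against 32.7% ± 2.71 (SD) over random placements, which is 2.25 times the random share (permutation p = 0.002, the smallest the placements can give). Introns held 26 summits (8.33%, random 25.4%, permutation p = 0.002), and 53 (16.99%, random 21.3%, permutation p = 0.0719) were intergenic. Coding exons held 0 of 312 (3 counts would be 0.962%), while random placements put 17.7% there (permutation p = 0.002). The strongest peaks of the replicates had promoter shares of 74.4%, 71.2%, 73.4% and 60.3% in replicates 1 to 4, a mean of 69.8% ± 6.50 (SD, n = 4), and a mean of 2.16% ± 0.843 (SD, n = 4) in coding exons. The weaker 3600 pooled peaks were in promoters in 52% of cases. Summits lay upstream of the nearest protein-coding start in 76.0% of cases, at a median signed distance of -294.5 bp. Within 500 bp of such a start lay 138 summits (44.2%, interval 38.6 to 49.9%), against 22.1% of random placements (permutation p = 0.002). In the replicates the share within 500 bp was 41.0% ± 4.48 (SD, n = 4).

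**Figure D1:**
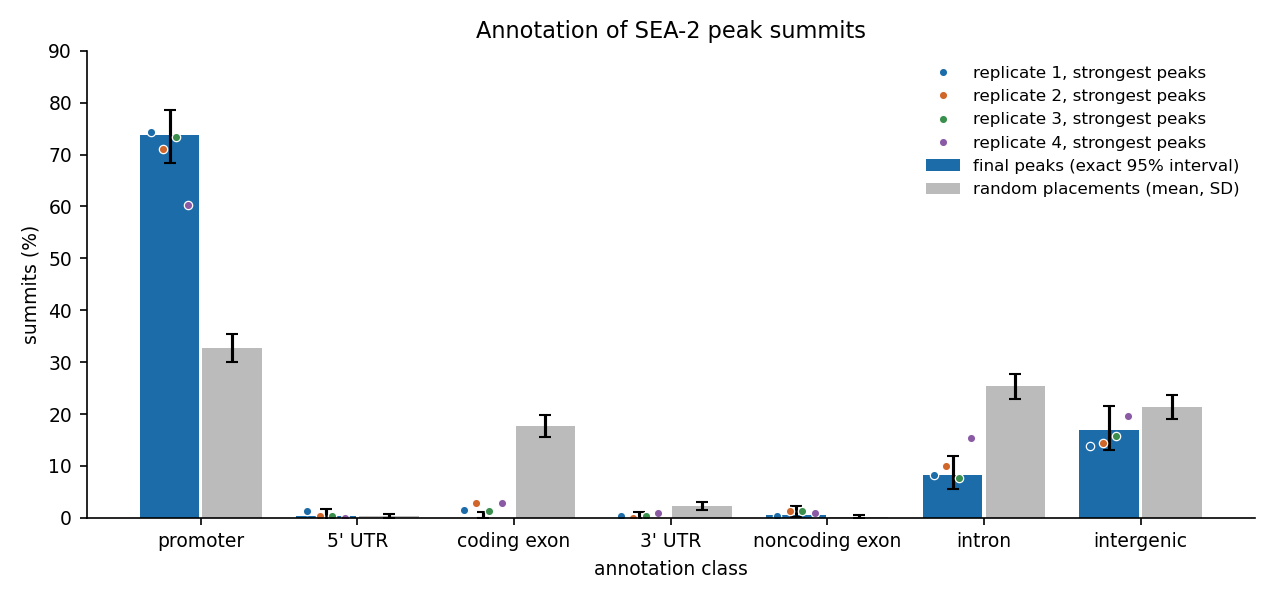
Share of summits (percent, vertical axis) in each annotation class (horizontal axis) for the final peaks, with exact 95% intervals, and for random placements, with their mean and SD; points are the strongest 312 peaks of each replicate. Promoters hold 73.7% of the final summits against 32.7% of random placements, and replicate 4 has the lowest promoter share, 60.3%.

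The X chromosome held more final peaks than its promoters would give, though it was not alone in departing from its share. Chromosome III had a larger ratio to its promoter-window length, 1.71, while chromosomes IV and V had ratios of only 0.673 and 0.419. On X lay 83 of 312 peaks (26.6%, 95% exact interval 21.8 to 31.9%), where X holds 18.1% of promoter-window length, a ratio of 1.47 (two-sided exact binomial test, p = 0.000219). Genes on X with such peaks included bet-2, the ribosomal protein gene rpl-11.2, the ER chaperone gene hsp-3 and the nuclear receptor gene nhr-1. Each replicate's strongest peaks had a share on X above 18.1%, at 26.9%, 31.4%, 25% and 22.8% in replicates 1 to 4, with a mean of 26.5% ± 3.68 (SD, n = 4). The weaker 3600 pooled peaks had 23.6% on X (849 peaks, interval 22.2 to 25.01%, exact binomial p = 2.04e-16), and the final peaks did not pass a test against them (Fisher's exact test, p = 0.239). Part of the difference lay at tRNA genes, of which X holds 276 of 612. Of the 16 final peaks within 500 bp of a tRNA gene 14 were on X, and without these 16 peaks the share on X was 23.3% (exact binomial p = 0.0234). In the 47, 55 and 52 final peaks found in each of the other replicates without replicates 1, 2 and 3 in turn, the share was 23.4%, 23.6% and 26.9% and the exact binomial p was 0.344, 0.293 and 0.105. Without replicate 4 it was 20 of 65 (30.8%, exact binomial p = 0.0143). All promoter-window lengths are from ce11.

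**Figure D2:**
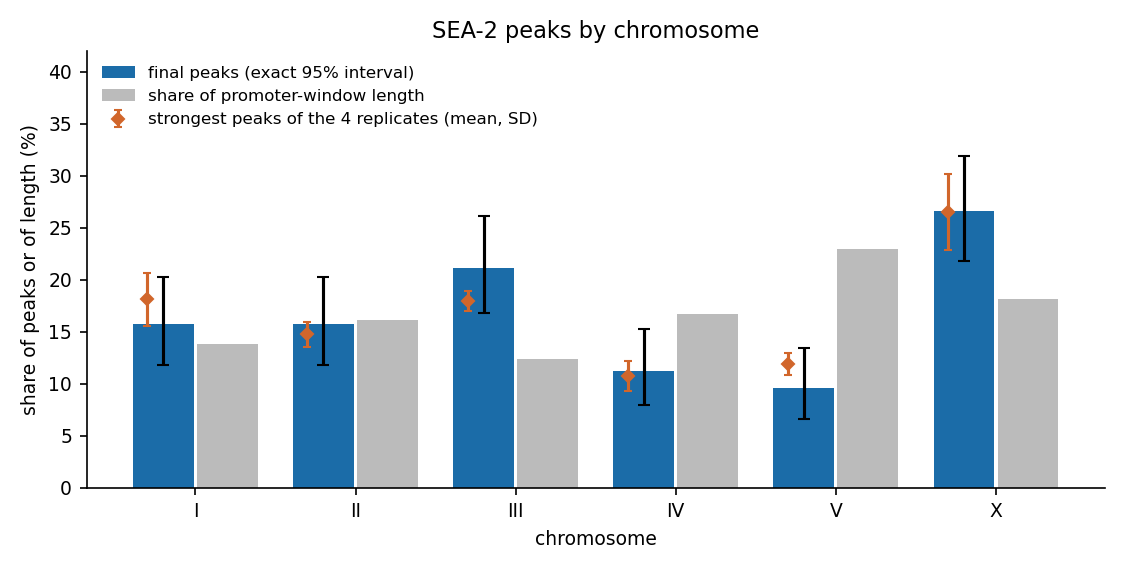
Share of peaks and share of promoter-window length (percent, vertical axis) for each chromosome (horizontal axis); bars with exact 95% intervals are the final peaks, and diamonds are the mean and SD of the strongest 312 peaks over the 4 replicates. On X the final peaks reach 26.6% against 18.1% of promoter-window length, and on V 9.62% against 22.9%.

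In all, 383 genes had a final summit in their promoter window, among them 222 of 19973 protein-coding genes (1.11%), 106 ncRNA, 23 tRNA, 15 snoRNA and 8 microRNA genes. Of the 22 gene lists, 6 were bound more often and 1 less often than other genes at an adjusted p under 0.05. No list was compared with the weaker pooled peaks. A preference common to promoter peaks in general was thus not told apart from one of SEA-2. Heat shock and stress genes had the highest share, with 5 of 28 bound against 1.09% of other protein-coding genes (odds ratio 19.8, Fisher's exact test, adjusted p = 9.49e-05). Its members were xbp-1, a transcription factor of the unfolded protein response (III, 4193626 to 4193965, signal value 88.0), the divergent small heat shock genes hsp-16.2 and hsp-16.41, which share a peak (V, 1805012 to 1805351, 80.7), and the chaperone genes hsp-3 (X, 6092067 to 6092406, 68.3) and hsp-1 (IV, 17278420 to 17278759, 68.3). The strongest peaks of the replicates bound 6, 1, 3 and 4 members in replicates 1 to 4, a mean of 3.5 ± 2.08 (SD, n = 4).

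Ribosomal protein genes were bound in 8 of 78 cases (10.3%, odds ratio 10.5, Fisher's exact test, adjusted p = 5.43e-05), each by its own peak. The strongest of these peaks were at rpl-11.2 (X, 2242842 to 2243181, signal value 102), rpl-18A (IV, 4749888 to 4750227, 102), rps-3A (III, 4475493 to 4475832, 87.5), rpl-3 (III, 3867414 to 3867753, 84.7), rpl-15 (IV, 654746 to 655085, 83.2) and rpl-35 (III, 7854506 to 7854845, 73.1). Replicates 1 to 4 bound 11, 5, 4 and 4 members, a mean of 6 ± 3.37 (SD, n = 4). Of the 72 histone genes 4 were bound, through 3 peaks, at his-67 and his-68, his-37 and the H3.3 gene his-72 (III, 12369052 to 12369391, signal value 77.5), with an odds ratio of 5.31 (Fisher's exact test, adjusted p = 0.0311) and a mean of 4.75 ± 0.957 members in the replicates (SD, n = 4).

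Small RNA genes made up further groups. Of 612 tRNA genes 23 were bound (3.76% against 1.25% of all other genes, odds ratio 3.08, Fisher's exact test, adjusted p = 7.36e-05), through 17 distinct peaks. The strongest were at the divergent pairs F46G11.t1 and F46G11.t2 (X, 5801145 to 5801484, signal value 117) and M02F4.t1 and M02F4.t2 (X, 3035939 to 3036278, 106) and at C28G1.t1 (X, 8835902 to 8836241, 103). ZK994.t2 was bound by a peak 903 bp upstream of its start (V, 8500369 to 8500708, signal value 97.9), which lay nearer to the snoRNA gene ZK994.7, at 40 bp. Replicates 1 to 4 bound 18, 28, 17 and 7 tRNA genes, a mean of 17.5 ± 8.58 (SD, n = 4), and the odds ratio of replicate 4 was 1.13 (Fisher's exact test, p = 0.681). All 16 final peaks within 500 bp of a tRNA gene had a near-identical copy of at least 50 bp elsewhere in the genome. Of 346 snoRNA genes 15 were bound (odds ratio 3.53, Fisher's exact test, adjusted p = 0.000308), in the replicates 13 ± 5.16 (SD, n = 4), the strongest being ZK20.9 (II, 11635030 to 11635369, signal value 132) and C06A1.9, whose peak also lay 150 bp upstream of cdc-48.1. ZK994.7 had the peak counted for ZK994.t2, K11H12.12 and K11H12.13 shared the rpl-15 peak, and W03C9.9 had a peak at II, 11960622 to 11960961 (signal value 81.0). Of the microRNA genes 8 of 261 were bound, including mir-71 and members of the mir-51 family, with an adjusted p of 0.0597 (Fisher's exact test). This call depends on the setting: the adjusted p was 0.0166 with a window of 2000 bp upstream (11 bound, odds ratio 2.54), 0.0366 without peaks that have a second copy, and 1 with summits assigned to the nearest start (2 bound, odds ratio 0.742).

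Chemoreceptor genes, which encode the odorant receptors of sensory neurons, were bound in 0 of 751 cases against 1.15% of other protein-coding genes (Fisher's exact test, adjusted p = 0.00211), where 3 counts would be a share of 0.399%. The list tests did not take the chromosome of a gene into account, and final peaks were few on chromosome V (ratio 0.419). How this list spreads over the chromosomes could therefore add to the difference. Of the 17 protein-coding heterochronic genes, which set the timing of larval development, 2 were bound (odds ratio 11.96, Fisher's exact test, adjusted p = 0.0471). They were nhl-2, 883 bp upstream of its start (III, 4899798 to 4900137, signal value 103), and lin-28. The lin-28 peak lay 51 bp downstream of an annotated start inside the gene. Replicates 1 to 4 bound 3, 4, 1 and 0 heterochronic members, and the nhl-2 peak lay nearer to the start of tag-340, at 540 bp. The final peak in a 5' UTR at lin-42 (II, 1236451 to 1236790), 348 bp downstream of an annotated start, lay outside the promoter window and was not counted. No sex determination and dosage compensation gene was bound (0 of 27, where 3 counts would be 11.1%). The lists for intestine, germline, hypodermis and seam cells, collagens, Hox and vulval genes, the Wnt pathway and translation factors also had 0 bound members, and none of them passed the test. The insulin and dauer list (2 of 28), neuron list (2 of 40), homeobox list (2 of 64), snRNA list (3 of 129), muscle list (1 of 40) and nuclear hormone receptor list (2 of 269) did not pass it either. With summits assigned to the nearest start, the adjusted p of the histone and snoRNA lists was 0.0715 (odds ratios 4.71 and 2.32), and 4 of 78 ribosomal protein genes were bound (odds ratio 5.89, Fisher's exact test, adjusted p = 0.0328). With a promoter window of 500 bp upstream to 100 bp downstream that of the heterochronic list was 0.251 (odds ratio 7.93) and the odds ratio of the ribosomal protein list 15.1, and in the stronger 50% of the final peaks those of the heterochronic list (odds ratio 10.3) and the chemoreceptor list (still 0 bound) were 0.27 and 0.0568. Among peaks found in at least 3 replicates the adjusted p was 0.257 for the heterochronic list (odds ratio 14.3) and 0.0586 for the snoRNA list (odds ratio 3.23), and the odds ratio of the histone list was 13.9. Among the 47 to 65 final peaks found in each remaining replicate when 1 was left out, the histone list passed in 4 of 4 cases. The heat shock and stress list passed without replicate 2, the ribosomal protein, tRNA and snoRNA lists without replicate 4, and the heterochronic list in no case. By construction each of these sets holds the 34 final peaks found in 4 of 4 replicates, among them those at his-67, his-68 and his-37. The 3 histone genes bound without replicate 1, 2 or 3 are these genes, so the histone passes are not separate tests. The odds ratios of these sets ran from 21.6 to 24.8 for the histone, 6.79 to 16.54 for the ribosomal protein and 1.86 to 5.47 for the tRNA list. For the heat shock and stress list the odds ratio was 59.7 without replicate 2 and 0 without replicates 1, 3 and 4. For the heterochronic list it was 24.9 without replicate 4 and 0 without replicates 1, 2 and 3. For the snoRNA list it was 0 without replicates 1 and 2, and 1.15 and 5.06 without replicates 3 and 4. The chemoreceptor list had 0 bound members in each of these sets and among peaks found in at least 3 replicates, where even 0 cannot pass with so few peaks, so these sets do not test it.

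**Figure D3:**
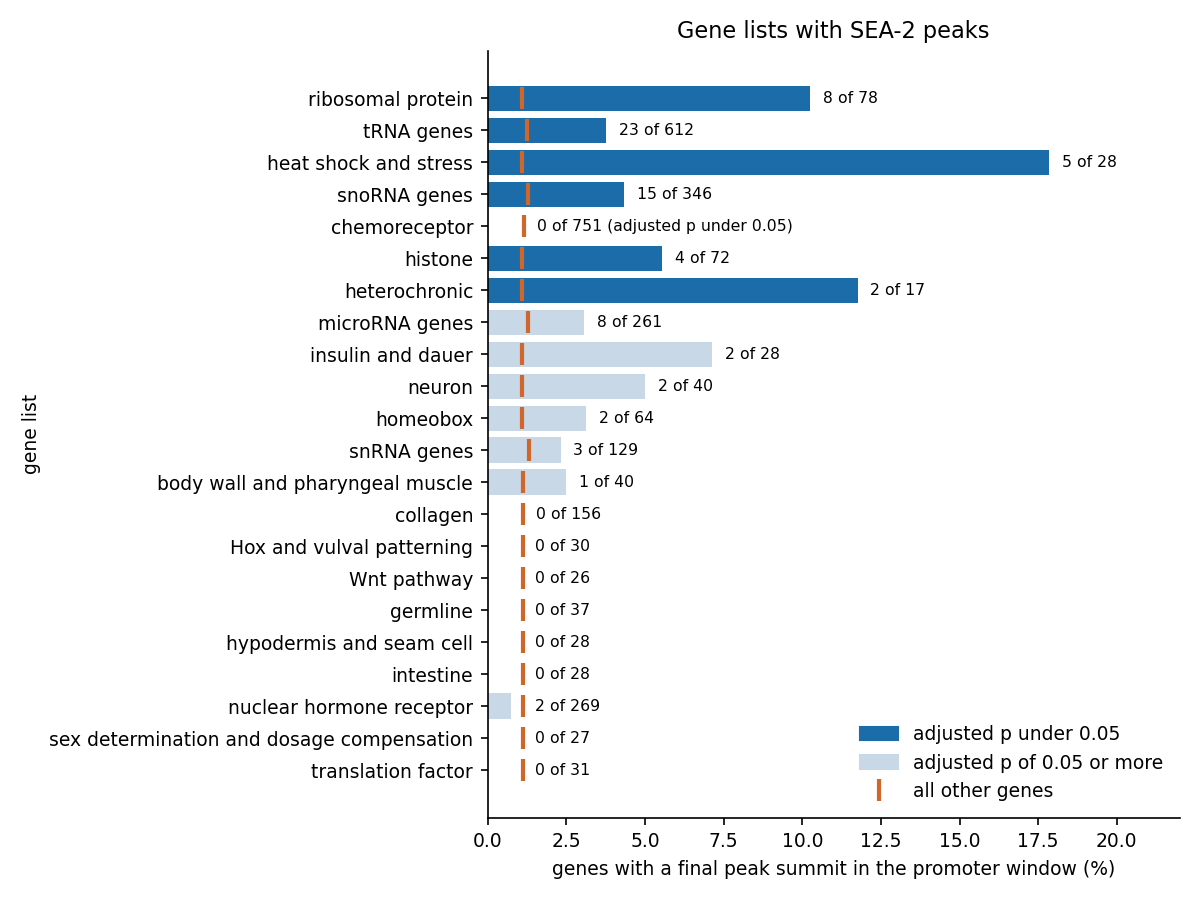
Share of genes with a final peak summit in their promoter window (percent, horizontal axis) for each of the 22 gene lists (vertical axis), with bound and total members beside each bar and the share among all other genes as a vertical mark. Heat shock and stress genes reach 5 of 28, and chemoreceptor genes 0 of 751.

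The gene of the tagged protein itself carried final peaks. In sea-2 (WBGene00004751, II, 3950377 to 3972140, plus strand) 2 final peaks lay in introns, at 3959725 to 3960064 (rank 29, signal value 111, with a second copy of part of its sequence in the genome) and 3958723 to 3959062 (rank 36, signal value 104.3), and no final peak lay in its promoter window. The best peak in the region of sea-2 with 5000 bp to each side ranked 29, 72, 17 and 5 in replicates 1 to 4. The transgene carries sea-2 and unc-119 sequence, so reads from it could map to both genes, which peak lists cannot show. At unc-119 (WBGene00006843, III, 10902641 to 10908935) there was no final peak, and the best rank in the pooled list was 3576 of 3912. At xol-1 (WBGene00006962, X, 8041313 to 8044409), the master switch of sex determination, there was no final peak within 5000 bp, and the best pooled peak, at 8036246 to 8036585, ranked 506. The region held 4, 5, 7 and 7 peaks in replicates 1 to 4, where random windows of its length had means of 3.02, 3.84, 4.06 and 3.79. At lin-28 (WBGene00003014, I, 8407630 to 8410804, minus strand), an RNA-binding heterochronic regulator, the final peak at 8409699 to 8410038 ranked 185 with a signal value of 70.04 and ranked 206, 213, 882 and 839 in replicates 1 to 4.

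Summits were GC-rich, and the 6-mer GAGAGA was more frequent at them than in the flanks. GC content within 50 bp of the final summits was 49.7%, against 36.7% in the flanking windows, a difference of 12.97 ± 0.514 percentage points (SE over peaks, permutation p = 1e-05, the smallest the sign flips can give). In the replicates' strongest peaks the difference was 10.1, 11.98, 10.1 and 5.87 points in replicates 1 to 4, a mean of 9.50 ± 2.58 (SD, n = 4). Of the 2080 6-mers, 281 were more frequent and 240 less frequent at summits at an adjusted p under 0.05. In the strongest peaks of replicates 1 to 4, 158, 231, 182 and 49 were more frequent and 129, 181, 149 and 28 less frequent. GAGAGA was present in 40.7% of summit windows and 9.46% of flanks (odds ratio 6.53, Fisher's exact test, adjusted p = 1.29e-24), CGTCTC in 25% and 4.33% (odds ratio 7.27, adjusted p = 2.15e-17) and CGCAGA in 20.8% and 3.04% (odds ratio 8.22, adjusted p = 1.02e-15). Their log2 odds ratios in the replicates' strongest peaks averaged 2.02 ± 0.23, 2.28 ± 0.62 and 2.38 ± 0.37 (SD, n = 4), above 0 in 4 of 4 replicates for each. AAAAAA was rarer at summits, in 8.65% against 41.0% of flanks. The 6-mer tests made no allowance for the GC difference, which alone can make words of A and T rarer at summits. They therefore do not show which 6-mers differ beyond GC content. They also treated flanks as independent of the summits beside them. In the 52 final peaks found in replicates 1, 2 and 4, without replicate 3, the odds ratio of GAGAGA was 4.26 with an adjusted p of 0.0594 (Fisher's exact test), and without replicates 1, 2 and 4 it was 8.63, 11.6 and 8.97 (adjusted p = 0.000671, 4.35e-06 and 1.18e-06).

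The replicates shared part of their strongest peaks, among them the linc-128, F44E5.4 and his-68 sites. Over the 6 pairs a mean of 31.0% ± 5.26 (SD over pairs) of the 312 strongest peaks were shared, from 25% between replicates 3 and 4 to 37.7% between replicates 1 and 2, while random shifts gave a mean of 0.125% and at most 7.69%. Random shifts leave out what the shared control and the shared preference for promoters add to the overlap. In replicate 1, 33 of its 312 strongest peaks were shared with each of the other replicates. Of the final peaks, 62.8% (95% exact interval 57.2 to 68.2%), 55.4% (49.7 to 61.0%), 53.5% (47.8 to 59.2%) and 39.1% (33.7 to 44.8%) were among the strongest peaks of replicates 1 to 4, a mean of 52.7% ± 9.93 (SD, n = 4). There were 34 final peaks (10.9%), including those at linc-128, F44E5.4, bet-2, nurf-1 and rpl-11.2, found in 4 of 4 replicates in this way, and 22 (7.05%), including the peak at the tRNA gene C33G3.t2, in none. Pairs within a label set, which include the highest and the lowest of the 6, shared 31.3% and pairs across sets 30.8%, a difference of 0.521 percentage points against an SD of 5.26 over pairs, and with 3 possible pairings of the replicates the smallest exact permutation p is 0.333, so the design cannot show a difference between them.

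**Figure D4:**
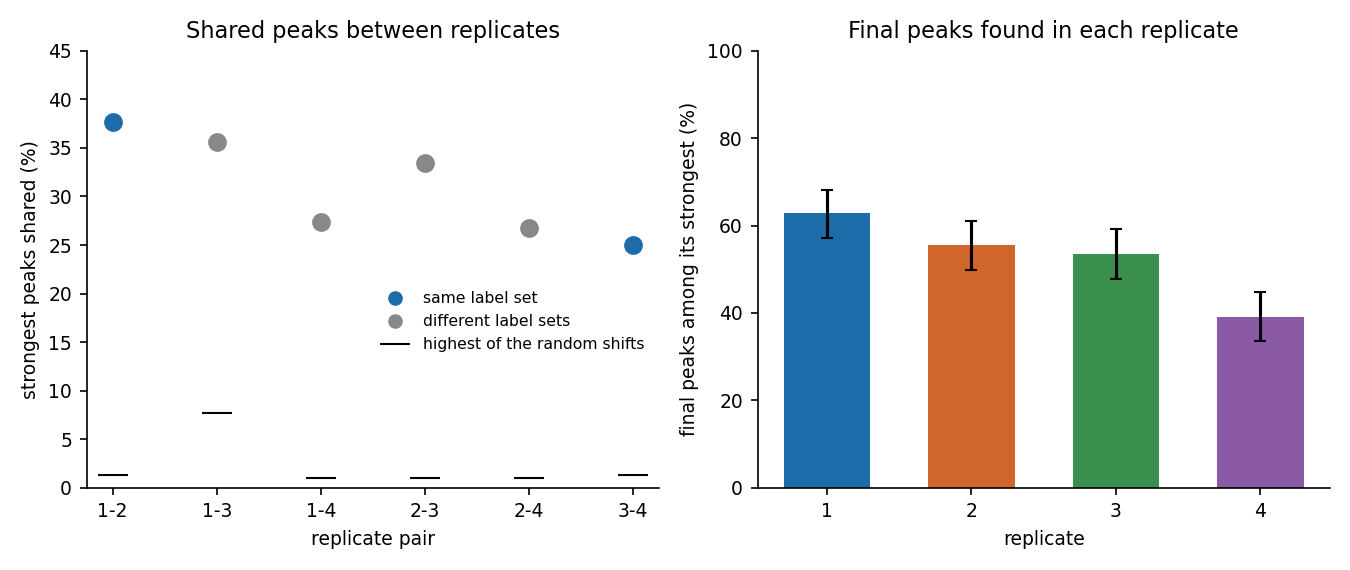
Left, share of the 312 strongest peaks (percent, vertical axis) shared by each replicate pair (horizontal axis), coloured by label set, with the highest of the random shifts as dashes. Right, share of the final peaks (percent, vertical axis) among the 312 strongest peaks of each replicate (horizontal axis) with exact 95% intervals, from 39.1% in replicate 4 to 62.8% in replicate 1.

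On ce10 the final list held 336 peaks, of which 95 (28.3%) were on X, beside 83 of 312 (26.6%) on ce11. Chromosome III held 68 final peaks on ce10 and 66 on ce11, and chromosome V held 31 and 30. The pooled lists held 3912 peaks on each build, and replicate 1 had 22984 peaks on ce10 and 23684 on ce11.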

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

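Apart from the assignment of summits to the nearest start, the tests of explanations in this part were chosen after the data had been seen, and the comparisons of the X share with the weakest regions and the weaker pooled peaks, and of sea-2 with the mean of genes of its length, were set after their own values were known. In 13 sets of replicate values compared for a replicate far from the others, where chance gives about 1 in 20, replicate 1 stood out with 11 ribosomal protein genes bound, against 5, 4 and 4 in the others. Replicate 4 bound 1 chemoreceptor gene and the others 0, a set in which any single count stands apart by construction, so it says nothing about that replicate.

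The share of final peaks on X was 26.6%, above the 18.1% of promoter-window length, and read depth on X was not tested. Chromosome III stood further above its own share in ratio, and chromosomes IV and V lay below theirs. Low counts on IV and V raise the shares of the other chromosomes. Without the 16 peaks near tRNA genes the share on X was 23.3% (exact binomial p = 0.0234). Without the 28 peaks that have a second copy in the genome it was 23.6% (exact binomial p = 0.0205). This argues against either alone as the whole cause of the excess over promoter-window length, the only baseline of these 2 tests. The weakest 5000 regions of the replicates had 19.97% ± 0.334 on X (SD, n = 4), and the strongest peaks exceeded them by 6.56 ± 3.83 percentage points, in 4 of 4 replicates, so the X share of the weakest regions does not account for the whole difference. An excess shared by the weaker pooled peaks stays open: 849 of 3600 (23.6%) lay on X, above promoter-window length and inside the interval of the final peaks, and Fisher's exact test between both gave p = 0.239, which does not show that they are equal. The shares of 23.3% and 23.6% above are close to that of the weaker pooled peaks, some of which can be background. An X excess of the final peaks beyond the weaker pooled peaks was therefore not shown. The design has no second group, so no biological explanation was tested.

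The peaks in sea-2 could come from extra copies of the locus on the transgene, which could add regions over the whole gene. The sea-2 region held more regions than 95% of random windows of its length in 3 of 4 replicates, with 18, 25 and 20 in replicates 2, 3 and 4 against random means of 9.30, 9.49 and 9.53, while replicate 1 had 6 against 7.45. The 255 other protein-coding genes within 25% of its length held on average 1.01 ± 0.0298 times the random mean (SD, n = 4), which argues against many regions around genes of this length in general, although a first test, which asked whether under 5% of them passed in at least 3 replicates, left it open (6 genes, 2.35%, 95% exact interval 0.868 to 5.05%). At unc-119, which is also on the transgene, the excess was seen in 1 of 4 replicates, while lin-28, which is not on it, passed in 2 and xol-1 in 0. Peak lists do not show how much of the unc-119 region, with 5000 bp to each side, the transgene carries. The count there therefore cannot show whether extra copies add regions. Extra copies of sea-2 are a candidate explanation, and attachment of SEA-2 to introns of its own gene stays open and was not tested.

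The tRNA genes are short, often divergent and similar in sequence, so their call could come from windows shared with neighbours, from peaks counted for several genes or from reads placed among copies. With each summit assigned to its nearest start Fisher's exact test gave p = 0.000658, and the 17 distinct peaks exceeded the mean of 5.44 from random positions in promoter windows (permutation p = 0.002), which argues against shared windows and repeated counting as the whole cause. Placement among copies stays open. All 16 peaks near tRNA genes have a second copy, so leaving out such peaks removes them by construction (Fisher's exact test, p = 0.0116, with tRNA genes then bound less often). No biological explanation was tested.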

How the results depend on the processing

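The settings that leave out peaks near tRNA genes or peaks with a second copy, and those that leave out a replicate for the X share, the distance to starts, the gene lists and the sequence tests, were chosen after the data had been seen. Of 165 recomputed values, 117 kept their direction and their side of the threshold or moved by less than the spread, 39 moved or lost their call, and 9 fell on the other side of no change. Of these 9, 8 are odds ratios of 0 in the small sets that leave out a replicate, with p = 1 (Fisher's exact test), where few members are expected and a 0 shows no change of direction, and the other is set by its construction. The promoter share stayed past its threshold in each setting tried, as did the GC difference. The share near coding starts ran from 44.2% to 46.2%, against 22.1% of random placements. In the smaller sets its p came from placements of all 312 peaks, whose spread is too narrow for fewer peaks. Those p-values are therefore too small, and these settings stay in the counts above. The mean overlap of replicate pairs fell from 31.0% to 17.2% with the 2000 and 13.6% with the 5000 strongest peaks, and the share of final peaks found rose from 52.7% to 82.9% and 89.98%. With peaks found in at least 3 replicates 4 gene lists passed in place of 7. The number of 6-mers past the threshold was 521, and 210 with windows of 25 bp to each side and 218 with the stronger 50% of the peaks. Final peaks found in each remaining replicate, leaving out 1 replicate in turn, number 47 to 65, which lowers the power of each test. These peaks still come from the final list of all 4 replicates, so the replicate left out helped to define them. Each was also required in every remaining replicate, so a lost call cannot be put down to the replicate left out. These sets gave 23.4% to 30.8% on X, 1 to 4 gene lists and 7 to 39 6-mers. Their odds ratios ran from 0, with no member bound, up to 59.7 for heat shock and stress, 24.9 for heterochronic and 5.06 for snoRNA genes, and were above 1 in each set for histone (21.6 to 24.8), ribosomal protein (6.79 to 16.54) and tRNA genes (1.86 to 5.47). The heat shock and stress list passed only without replicate 2, and the snoRNA, tRNA and ribosomal protein lists only without replicate 4. The histone list passed in 4 of 4 cases and the heterochronic list in none. By construction each of these sets holds the 34 final peaks found in 4 of 4 replicates, among them those at his-67, his-68 and his-37. The chemoreceptor list had 0 bound members in these sets and among peaks found in at least 3 replicates, where it could not pass, so its lost calls there, which stay in the counts above, say nothing about it. The odds ratio of tRNA genes went from 3.08 to 0.139 without peaks that have a second copy, a setting that removes the peaks near tRNA genes by its construction. For the other changes the cause was not tested. The label sets need 4 replicates, so no replicate was left out there. No paired analysis was possible because the labels give 1 group. Unknown read depth limits how far ranks near the end of the lists can be read.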

Other observations

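Tests in this part were chosen after the data had been seen. The autosomes differed from each other in their share of final peaks. Chromosome III held 66 peaks where promoter-window length would give 38.6 (ratio 1.71, exact binomial test, adjusted p = 4.23e-05 over 6 chromosomes), and its share was above the expected 12.4% in 4 of 4 replicates, with a mean of 17.9% ± 0.944 (SD, n = 4). Chromosome V held 30 where 71.6 were expected (ratio 0.419, exact binomial test, adjusted p = 7.88e-09), and chromosome IV held 35 where 52 were expected (ratio 0.673, exact binomial test, adjusted p = 0.0144), each below expectation in the strongest peaks of 4 of 4 replicates. Chromosomes I and II, with 49 peaks each, did not pass the test (adjusted p = 0.389 and 0.939, exact binomial test).

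Among tRNA genes, 20 of 276 on X (7.25%) and 3 of 336 on the autosomes (0.893%) were bound, an odds ratio of 8.67 (Fisher's exact test, p = 4.48e-05). The same comparison gave odds ratios of 2.5, 7.90, 4.10 and 1.63 in the strongest peaks of replicates 1 to 4, with p = 0.0902, 7.71e-06, 0.0117 and 0.707 (Fisher's exact test). Bound tRNA genes share peaks, so these genes are not independent of each other.

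Several of the frequent 6-mers overlap in the 10-base word GAGACGCAGA. Of 12 words of this length seen in at least 10 summit windows it had the lowest p, with 35 of 312 summit windows (11.2%) and 3 of 624 flanking windows (0.481%), an odds ratio of 26.2 (Fisher's exact test, adjusted p = 1.83e-13). Replicates 1 to 4 had it in 30, 30, 25 and 20 of their strongest summit windows and in 5, 4, 8 and 5 of the flanking windows. The words were picked for their frequency at summits, so these p-values are too small. Nor was the GC difference between summits and flanks taken into account. Of the 35 final peaks with the word, 21 lay in a promoter window and 6 on X.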
